A study of Homo sapiens with 24 samples.

How the data were processed

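The data are 24 scanner files of a 2-colour Agilent whole human genome array, design 014850, 1 per sample, and the value table the authors deposited for the same arrays. Per the file headers, each slide was scanned and read with Feature Extraction 10.10.1.1, and the probe annotation refers to build hg18. Per the labels, Cy3 marked the co-cultured Caco-2 sample and Cy5 a common reference of untreated Caco-2 cells from conventional culture on every array, so each log ratio was turned as sample over reference and none needed a change of sign. Per the submitters' processing notes, R 2.15.1 and limma were used; the settings were not given in the sources used here. Each file held 45015 spots, of which 1639 were controls and 43376 carried 41000 distinct probes. The scanner files hold a median intensity and a background intensity per channel and spot, per the file headers, on a linear scale, and the software's own processed signals. The deposited value table holds log2 ratios: on each array they differed from loess-normalised log2 ratios of Cy3 over Cy5 computed here without background correction by a median of 0.00131 and at most 0.0944, with array correlations from 0.99988 to 0.99999. That settles their log base, centring (array medians between -0.0138 and 0.009) and direction.

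The median intensities of the deposited scanner files were corrected for background with normexp and an offset of 50 in limma 3.58.1 under R 4.3.3. Means per spot were not used. Log ratios were normalised by loess within each array, with control spots and spots the software marked as outliers at weight 0, and both were left out afterwards. Replicate spots of a probe were averaged. Probes were kept when they were well above background in Cy3 on at least 6 of 24 arrays and had values on at least 3 arrays of each group, which left 28329 probes, and the probe of highest mean signal stood for a gene, which left 22102 genes. For 4869 genes more than 1 probe passed. In the comparisons for which a gene is named in the text, no other probe of it had the opposite sign at an unadjusted p below 0.05. The accession given for each probe was matched without its version to a RefSeq gene table of assembly GRCh38.p14 for symbols. Of the 41000 probes 23958 matched, over 16557 symbols, and 17042 kept the name in the file. No coordinates are given because the builds differ. Gene lists were matched by symbol, so a probe without one entered no list and its gene may be missing there. No Cy3 spot was saturated.

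Linear models were fitted in limma to all 24 arrays with 1 mean per group and a shared spread, and moderated by eBayes. The contrasts were live F. prausnitzii, UV-killed F. prausnitzii and L. rhamnosus against no bacteria, live against UV-killed F. prausnitzii, live F. prausnitzii against L. rhamnosus, and the mean without bacteria against 0, which is the reference. The p-values were adjusted by Benjamini-Hochberg over the 22102 genes of a comparison, and a gene counts as higher or lower, or is said to have risen or fallen, at an adjusted p below 0.05. Standard errors are limma's. Gene lists, 23 with 481 entries, were tested with camera at a preset inter-gene correlation of 0.01, over the 21784 genes measured on all arrays, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Lists, the tests of genes and lists, most alternatives and the rule for named genes were set before the data were examined; the alternatives and tests chosen later are named where they are given. The rule names, among called genes with a symbol, the 10 largest rises and 10 largest falls with at least 5 of 6 arrays on the same side of the other group's mean, up to 4 called members of each list by size, and for a list that passed camera its up to 4 members of smallest p as values; where fewer than 5 genes were called, it names the 10 symbols of smallest p as values. A gene that was not well above background on any array of a group would have been given only a lower limit of its fold; no gene named here was in that position, and for those measured on part of a group's arrays the number is given. The labels describe the 6 samples of a group as biological replicates. The number of arrays limits the precision.

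The slides (6, with 4 arrays each) held 1 array of each group, and all were scanned on 1 day; slide was fitted as a block as an alternative. The groups share replicate numbers in the labels, and a fit with that number as a block was also made. The main counts come from the fit without it, so they leave out any structure shared by a number. Other alternatives were no background correction, the software's processed signals, median centring, Aquantile after loess, Cy3 alone with quantile normalisation, the deposited values, no filter and a filter on all 24 arrays, all probes, eBayes with trend and robust settings, array weights, fits of 2 groups alone, a 1.5-fold minimum and leaving out single arrays. The fit was tested on simulated data. With 200 genes changed among 22102 for live F. prausnitzii against no bacteria, drawn in 5 runs from the means and spreads of the real genes, 46.0% of changes of 0.5 on the log2 scale were recovered, 93.6% of changes of 1.0, 98.0% of changes of 1.5 and 90.4% of changes of -1.0, with 5.1% of calls false. A list of 30 genes shifted by 0.5 passed camera in 5 of 5 runs and an unshifted one in 0. Each value was drawn independently, so these runs hold no correlation between genes and no structure shared by arrays. They do not test the calls or camera where such correlation or structure is present.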

Results

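Gene expression was measured in Caco-2 cells, an established human colon adenocarcinoma line that forms a polarised epithelial layer resembling the small intestine when it is grown on a permeable filter. The layers were grown for 14 days and then kept for 4 hours in a chamber in which the side facing the gut lumen was free of oxygen. That side held one of 4 additions: no bacteria, live Faecalibacterium prausnitzii, F. prausnitzii killed with ultraviolet light, or Lacticaseibacillus rhamnosus HN001 (L. rhamnosus in the labels). F. prausnitzii is an obligate anaerobe and an abundant butyrate producer of the human colon, and L. rhamnosus HN001 is a probiotic strain. Bacteria were given at 100 per cell. Each group had 6 biological replicates, each on its own 2-colour array, which makes 24 arrays. Every array carried the sample in the Cy3 channel and one common reference, untreated Caco-2 cells from conventional culture, in the Cy5 channel. No array had the dyes swapped. The values below are log2 ratios of sample over reference, and differences between groups are differences of these ratios, on the log2 scale unless a fold is given. Of the probes for genes, between 57.9% and 75.3% were well above background in Cy3 on an array, and the median Cy3 signal ran from 125 to 469.75 units. The highest signal was on the array of UV-killed replicate 6 and the next, 401 units, on that of L. rhamnosus replicate 6. The log ratios of any pair of arrays correlated with r between 0.437 and 0.971 across genes, which are not independent replicates. Each of the 6 slides held 1 array of every group. Expression was tested for 22102 genes, of which 13086 had a current symbol.

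The comparison of live F. prausnitzii with no bacteria asked which epithelial genes respond to the living anaerobe. Live bacteria raised a set of chemokine and NF-kB target genes by large factors. CXCL1, which attracts neutrophils, was 17.6-fold higher (log2 difference 4.14 ± 0.53 SE, adjusted p = 4.01e-05), at 5.35 ± 0.33 (SD, n = 6) against 1.21 ± 1.21 (SD, n = 6) without bacteria. The monocyte attractant CCL2 was 14.4-fold higher and CCL20, which attracts dendritic cells and lymphocytes through CCR6, was 12.4-fold higher. CXCL2 was 10.7-fold and CXCL3 8.73-fold higher, and CCL4 was 4.64-fold higher. CXCL8 (interleukin 8) was 6.76-fold higher, with a signal well above background on 6 of 6 live arrays and on 2 of 6 arrays without bacteria. The lymphotoxin gene LTB was 7.10-fold higher, BIRC3, an inhibitor of apoptosis, 8.78-fold higher, and ZC3H12A, an RNase that degrades inflammatory transcripts, 5.37-fold higher. Adjusted p for these genes ran from 2.74e-07 to 4.93e-05. Each of these 10 genes was higher with live bacteria on 6 of 6 slides, and on all 6 live arrays it lay above every array without bacteria. The probes for CXCL1, CXCL2 and CXCL3 detect closely related transcripts, so their separate values are uncertain.

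**Figure D1:**
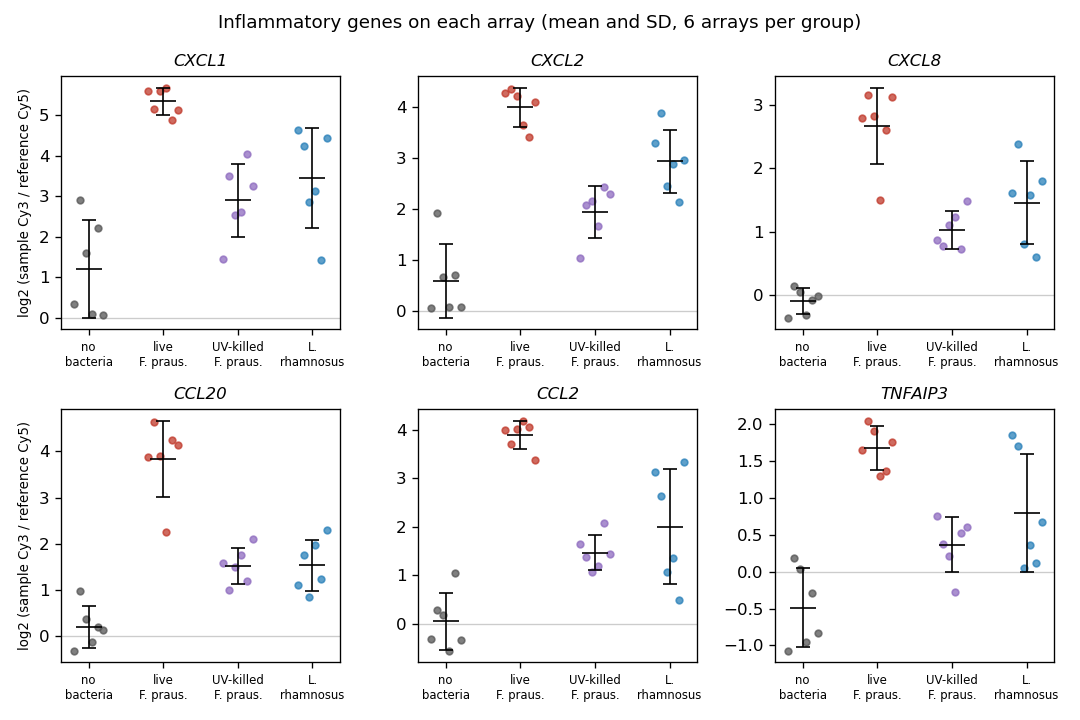
Log2 ratio of sample over reference for 6 inflammatory genes; each point is 1 array, in slide order within a group, and the bar and whiskers are the mean and SD of 6 arrays. CXCL1 averaged 5.35 with live F. prausnitzii and 1.21 without bacteria.

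In all, 106 genes rose and 0 fell at an adjusted p below 0.05 in limma, and 49 of them rose by at least 2-fold. At an unadjusted p below 0.05 there were 537 genes, where 1105 are expected by chance among independent tests. Of the fixed list of NF-kB targets and inflammatory mediators, 20 of 31 measured members rose, 0 fell and 11 did not pass; 26 rose when adjusted over the list alone. The list's median difference was 1.42 (camera adjusted p = 1.02e-134; adjusted p = 1.55e-08 with an estimated correlation). Its members included the adhesion molecule ICAM1 (1.61 ± 0.14 SE, adjusted p = 2.74e-07). Of 28 measured immediate early and MAPK feedback genes, 4 rose and 0 fell: IER3 by 1.63 ± 0.21, ZFP36, which destabilises cytokine transcripts, by 1.29 ± 0.26 (5 arrays without bacteria), PHLDA1 by 1.00 ± 0.14, and the growth factor EREG by 0.71 ± 0.14 (SE; adjusted p from 4.34e-05 to 0.0135). That list shifted by a median of 0.42 (adjusted p = 3.68e-23; adjusted p = 4.13e-05 with an estimated correlation), with 14 members higher when adjusted over the list alone. Among 16 genes of microbe sensing, the adaptor TICAM1 rose by 0.95 ± 0.17 and the kinase RIPK2 by 0.51 ± 0.10, and the list as a whole did not pass (adjusted p = 0.0759). CXCL10 was the 1 of 18 interferon-stimulated genes that rose (1.24 ± 0.15 SE, adjusted p = 2.39e-05), with a signal well above background on 1 of 6 arrays without bacteria, and that list did not pass (adjusted p = 0.338).

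Aryl hydrocarbon receptor targets, 7 measured genes, shifted by a median of 0.39 (adjusted p = 2.14e-05; adjusted p = 0.00172 with an estimated correlation) although 0 members passed alone; CYP1A1 differed by 0.48 ± 0.18 (SE) and CYP1B1 by 0.53 ± 0.29. The p53 and apoptosis list had a median of 0.09 (camera adjusted p = 0.00027, and adjusted p = 0.00799 with an estimated correlation). PMAIP1, higher by 0.74 ± 0.16 (adjusted p = 0.0264), was its 1 called member of 16. When 1 array was left out, the list's median ran from 0.04 to 0.18. No member of the tight junction list passed among 22 measured (median -0.03, adjusted p = 0.338), and none passed in the hypoxia list of 28 (median 0.02, adjusted p = 0.208), the mucin and antimicrobial list of 15 (adjusted p = 0.208) or the butyrate transport and response list of 16 (adjusted p = 0.0759). With slide as a block 101 genes rose, 100 of them among the 106, and within single slides the NF-kB list's median difference lay between 1.24 and 1.66. With replicate number as a block 143 genes rose and 0 fell. Median centring of each array in place of loess left 36 genes, and array weights gave 229, of which 196 were higher and 33 lower.

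**Figure D2:**
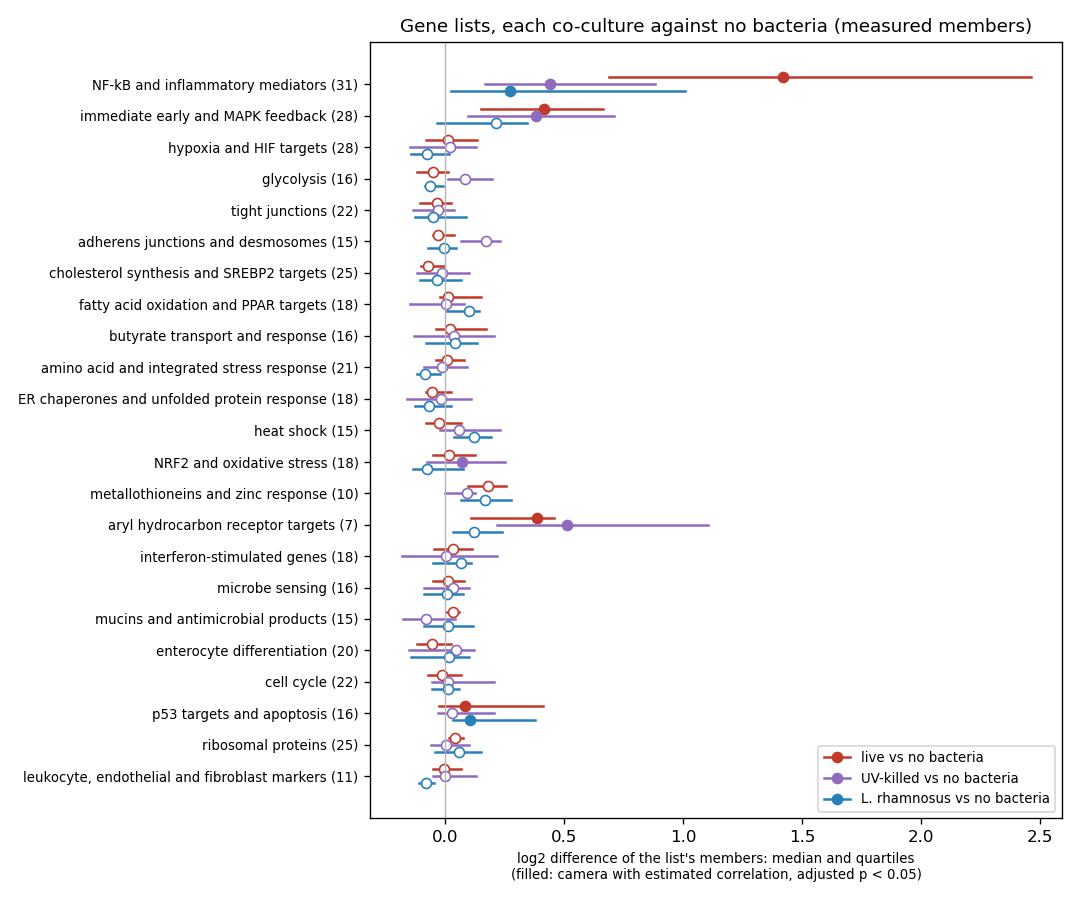
Median (point) and quartiles (line) of the log2 difference over the measured members of 23 gene lists, for each co-culture against no bacteria; filled points pass camera with an estimated correlation at an adjusted p below 0.05. The NF-kB list stands at 1.42 with live F. prausnitzii, 0.44 with UV-killed F. prausnitzii and 0.28 with L. rhamnosus.

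The comparison of UV-killed F. prausnitzii with no bacteria asked what the same organism does once killed. HBEGF, a ligand of the EGF receptor, rose by 1.26 ± 0.14 (SE, adjusted p = 3.15e-05), from -0.18 ± 0.16 to 1.08 ± 0.34 (SD, n = 6 in each group). SLC7A5, a subunit of the large neutral amino acid transporter, rose by 1.28 ± 0.16, and SPRED1, an inhibitor of MAPK signalling, by 1.27 ± 0.18. The small MAF transcription factor MAFF rose by 1.20 ± 0.13, the nuclear receptor coactivator NCOA7 by 1.17 ± 0.11, SPRING1, which is needed for SREBP activation, by 1.02 ± 0.12, the transcriptional regulator SERTAD2 by 0.98 ± 0.12 and EREG by 0.97 ± 0.14. TIPARP, a repressor of the aryl hydrocarbon receptor, rose by 1.14 ± 0.18 and CYP1A1, the receptor's classical target, by 1.07 ± 0.18. Adjusted p for these 10 genes ran from 4.24e-06 to 0.00317, and each was higher on 6 of 6 slides.

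In all, 37 genes rose and 1 fell, 9 of the 38 by at least 2-fold. The 1 fall was of an unnamed transcript, by 0.56. Of 7 measured aryl hydrocarbon receptor targets, 2 rose and 5 did not pass, and 4 were higher when adjusted over the list alone; the list's median was 0.51 (adjusted p = 4.32e-10; adjusted p = 9.06e-05 with an estimated correlation) and lay between 0.33 and 0.71 within single slides. CYP1B1 differed by 1.21 ± 0.29 (SE, adjusted p = 0.116). Immediate early and MAPK feedback genes shifted by a median of 0.38 (adjusted p = 2.9e-17; adjusted p = 0.000293 with an estimated correlation), with HBEGF, EREG and PHLDA1 (0.93 ± 0.14) as the 3 called members of 28 and 13 higher when adjusted over the list alone. The NF-kB list shifted by a median of 0.44 (adjusted p = 6.76e-18; adjusted p = 0.00632 with an estimated correlation), with 1 of 31 members called, the IkB family member NFKBIZ (0.91 ± 0.19 SE, adjusted p = 0.0466), and 14 higher when adjusted over the list alone. CXCL2 differed by 1.36 ± 0.31 (adjusted p = 0.0896), CCL20 by 1.32 ± 0.31 (adjusted p = 0.119) and CXCL8 by 1.13 ± 0.26 (adjusted p = 0.102). The NRF2 list passed with a median of 0.07 (adjusted p = 0.0259; adjusted p = 0.0489 with an estimated correlation) and 0 called members, TXNRD1 differing by 0.94 ± 0.24. With an estimated correlation it did not pass without any of no-bacteria replicates 3, 4 and 5 or UV-killed replicates 1, 2, 3 and 4 (adjusted p from 0.0612 to 0.124). Passing only with the preset correlation were adherens junctions and desmosomes (median 0.17; adjusted p = 0.194 with an estimated correlation), glycolysis (0.09; adjusted p = 0.223), heat shock (0.06; adjusted p = 0.114), p53 targets (0.03; adjusted p = 0.0819) and the amino acid and integrated stress response (median -0.01 and mean and test above 0; adjusted p = 0.194); 0 members were called except SLC7A5 in the last. On UV-killed replicate 6, the array of highest Cy3 signal, the mean log ratio of the glycolysis list was 0.0841 and that of the heat shock list -0.751, and on the other 5 arrays of the group the highest were -0.267 and -0.886.

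**Figure D3:**
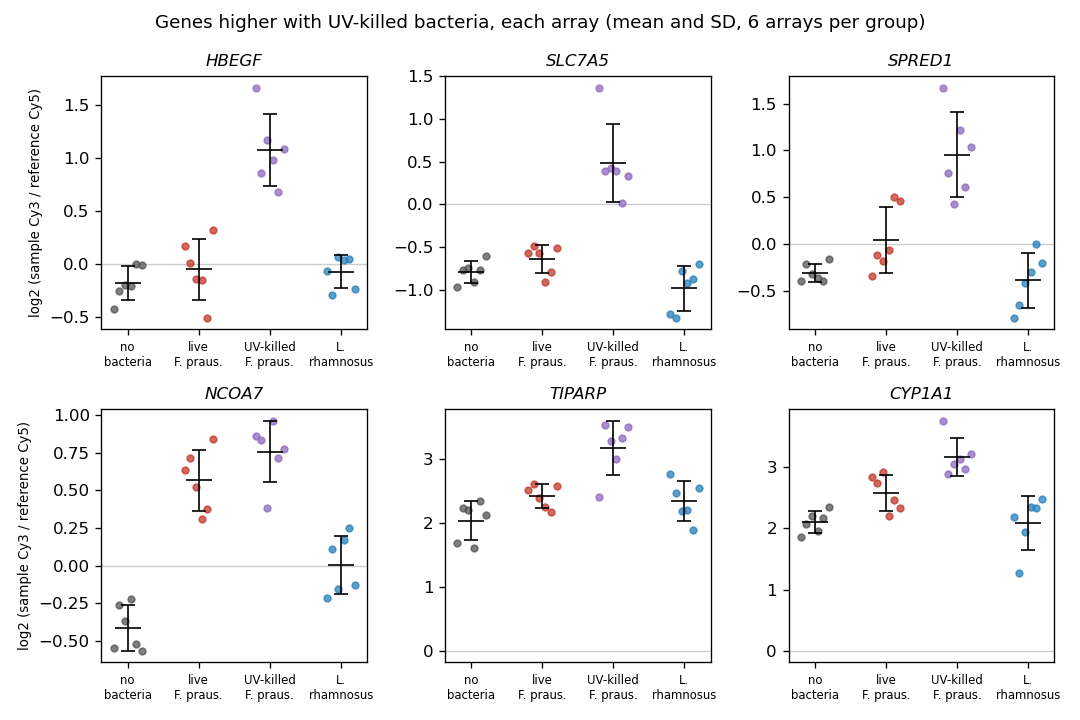
Log2 ratio of sample over reference for 6 genes called higher with UV-killed F. prausnitzii; each point is 1 array, in slide order within a group, and the bar and whiskers are the mean and SD of 6 arrays. HBEGF averaged 1.08 with UV-killed bacteria and -0.18 without bacteria.

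With slide as a block 29 genes rose and 0 fell, all of them among the 38. With replicate number as a block 65 rose and 3 fell. The scanner software's processed signals gave 72 genes, values without background correction gave 69, median centring left 1 and array weights gave 135, of which 108 were higher and 27 lower.

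L. rhamnosus against no bacteria asked which genes respond to a lactic acid bacterium given live. It raised 3 genes and lowered 0: CXCL2 by 2.35 ± 0.31 (SE, adjusted p = 0.00175), which is 5.10-fold, CXCL8 by 1.55 ± 0.26 (adjusted p = 0.0331), and a transcript without a matched symbol, NM_004024, by 0.92 ± 0.16 (adjusted p = 0.0331), which was not chosen by the rule for named genes. CXCL2 stood at 2.93 ± 0.62 (SD, n = 6) against 0.58 ± 0.72 (SD, n = 6) and was higher on 6 of 6 slides. CXCL8 was also higher on 6 of 6 slides, with a signal well above background on 6 of 6 arrays against 2 of 6 without bacteria. Of the 31 NF-kB genes 2 rose, and 10 were higher when adjusted over the list alone; the list's median was 0.28 (adjusted p = 1.03e-13; adjusted p = 0.03 with an estimated correlation), and within single slides it ran from -0.05 to 0.75, above 0 on 5 of 6; the slide below 0 held L. rhamnosus replicate 6 and no-bacteria replicate 1. With an estimated correlation the list did not pass without any of L. rhamnosus replicates 2 and 3 or no-bacteria replicates 1, 4, 5 and 6 (adjusted p from 0.0503 to 0.103). Other members with small p were CCL2 (1.95 ± 0.38 SE, adjusted p = 0.141), CXCL3 (1.75 ± 0.37, adjusted p = 0.275) and TNFAIP3, which encodes the NF-kB inhibitor A20 (1.28 ± 0.29, adjusted p = 0.322). Outside the list, KLF6 differed by 1.03 ± 0.20 (adjusted p = 0.149), the endothelin gene EDN1 by 0.88 ± 0.19, GADD45B by 0.78 ± 0.17, DUSP1 by 1.12 ± 0.25, RHOU by -0.44 ± 0.09 and CCDC71L by -0.37 ± 0.08, none of which passed.

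The p53 and apoptosis list had a median of 0.11 (adjusted p = 0.00109; adjusted p = 0.03 with an estimated correlation) with 0 of 16 members called, GADD45A differing by 0.54 ± 0.13 and BTG2 by 0.64 ± 0.19. With an estimated correlation this list did not pass without any of L. rhamnosus replicates 3 and 6 or no-bacteria replicates 1, 4, 5 and 6 (adjusted p from 0.053 to 0.0953). The immediate early list (median 0.22; adjusted p = 0.000135) and the heat shock list (median 0.12; adjusted p = 0.0242) passed only with the preset correlation, their adjusted p with an estimated correlation being 0.0997 and 0.111. At an unadjusted p below 0.05 there were 1277 genes, against 1105 expected by chance. The count was fragile: 2 genes passed with slide as a block, 0 when only the 12 arrays of the 2 groups were fitted and 131 with array weights, of which 67 were higher and 64 lower. The transcript lost with slide as a block was NM_004024 (adjusted p = 0.202). The count was 8, with 0 lower, with replicate number as a block. It was 1 without any of L. rhamnosus replicates 1, 3 and 5 or no-bacteria replicates 2, 3, 4, 5 and 6, and 6 without no-bacteria replicate 1.

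Live against UV-killed F. prausnitzii compared the living organism with the killed preparation. Loss of viability and other effects of the ultraviolet treatment cannot be told apart in this design. Live bacteria gave higher levels of 75 genes and lower levels of 20. CXCL1 was higher with live bacteria by 2.45 ± 0.53 (SE, adjusted p = 0.028), CCL2 by 2.43 ± 0.38, LTB by 2.36 ± 0.37, CCL20 by 2.32 ± 0.31, CXCL2 by 2.06 ± 0.31, IL23A, a subunit of interleukin 23, by 1.74 ± 0.26, CCL4 by 1.69 ± 0.20 and CXCL8 by 1.63 ± 0.26, with adjusted p from 5.21e-05 to 0.00136 for the last 7. Of the 31 NF-kB genes, 17 were higher and 0 lower, 23 higher when adjusted over the list alone, with a median of 0.86 (adjusted p = 1.12e-40; adjusted p = 0.000181 with an estimated correlation) that lay between 0.78 and 1.23 within single slides. IL1B differed by 1.25 ± 0.17 and the mitochondrial superoxide dismutase gene SOD2 by 0.77 ± 0.11. CXCL10 was higher by 0.84 ± 0.15 and TICAM1 by 0.84 ± 0.17.

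The genes lower with live than with UV-killed bacteria included HBEGF (-1.12 ± 0.14 SE, adjusted p = 0.000103), SLC7A5 (-1.12 ± 0.16), SERTAD2 (-0.95 ± 0.12), SPRED1 (-0.92 ± 0.18), the epithelial transcription factor GRHL3 (-0.89 ± 0.14), the potassium channel gene KCNJ8 (-0.87 ± 0.14), SPRING1 (-0.87 ± 0.12), the peptide hormone gene APLN (-0.87 ± 0.13), FGFBP1, which releases fibroblast growth factors from the matrix (-0.82 ± 0.16), and the Notch ligand DLL1 (-0.80 ± 0.12). Each was lower with live bacteria on 6 of 6 slides. Aryl hydrocarbon receptor targets were lower with live bacteria as a list (median -0.17, adjusted p = 0.00224; adjusted p = 0.0278 with an estimated correlation), with 0 members called and 2 lower when adjusted over the list alone. TIPARP differed by -0.76 ± 0.18 (adjusted p = 0.0546) and CYP1A1 by -0.59 ± 0.18 (adjusted p = 0.322). Within single slides that list's median ran from -0.67 to 0.25, and it was above 0 on 1 of 6. With an estimated correlation it did not pass without any of live replicates 1, 3, 4 and 5 or UV-killed replicates 2, 4 and 5 (adjusted p from 0.0513 to 0.085). The adherens junction and desmosome list (median -0.25) and the glycolysis list (median -0.13) passed only with the preset correlation (adjusted p = 0.000661 and 0.00298, against adjusted p = 0.178 for both with an estimated correlation). With slide as a block 62 genes were higher and 20 lower, and with replicate number as a block 118 were higher and 29 lower. Fitting only the 12 arrays of the 2 groups gave 45 genes, median centring gave 14, and array weights gave 213, of which 144 were higher and 69 lower.

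Live F. prausnitzii against L. rhamnosus compared the living organisms. Live F. prausnitzii gave higher levels of 84 genes and lower levels of 1, an unnamed transcript. CCL20 was 4.95-fold higher (2.31 ± 0.31 SE, adjusted p = 0.000201), BIRC3 3.93-fold higher (1.98 ± 0.35), LTB 3.91-fold higher and CCL2 3.71-fold higher. TNFAIP2 was higher by 1.87 ± 0.26, ZC3H12A by 1.80 ± 0.22, the membrane chemokine CX3CL1 by 1.74 ± 0.18, the urokinase gene PLAU by 1.71 ± 0.22, CCL4 by 1.64 ± 0.20 and the acute phase gene SERPINA3 by 1.55 ± 0.17. Of the 31 NF-kB genes, 15 were higher and 0 lower, 24 higher when adjusted over the list alone, with a median of 0.99 (adjusted p = 3.31e-53; adjusted p = 2.81e-05 with an estimated correlation) and medians within single slides from 0.54 to 1.43. ICAM1 differed by 1.40 ± 0.14 and IL1B by 1.17 ± 0.17. IER3, PHLDA1 and SPRY4, the last well above background on 5 of 6 L. rhamnosus arrays, were the 3 called members of the immediate early list, which passed with the preset correlation (median 0.25, adjusted p = 0.000273) and not with an estimated one (adjusted p = 0.117). TICAM1 (0.76 ± 0.17) and RIPK2 (0.48 ± 0.10) were the 2 called genes of microbe sensing. The hypoxia list (median 0.08) and the heat shock list (median -0.09) passed with the preset correlation at an adjusted p of 0.0476 each, and neither did with slide as a block (adjusted p = 0.0528 and 0.0615) or with an estimated correlation (adjusted p = 0.117 and 0.135). With slide as a block 67 genes were higher and 0 lower, and with replicate number as a block 149 were higher and 15 lower. Without L. rhamnosus replicate 4 the count was 51, and without UV-killed replicate 6, which enters only through the shared spread, it was 143; median centring gave 14, the 12 arrays of the 2 groups alone 48, and array weights 233, of which 194 were higher and 39 lower.

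The 3 responses were also set against each other across all genes tested. The differences from no bacteria correlated with r = 0.362 between live and UV-killed F. prausnitzii, 0.363 between live F. prausnitzii and L. rhamnosus, and 0.094 between UV-killed F. prausnitzii and L. rhamnosus. For unchanged groups, the arrays' deviations from their group means were dealt at random to the 4 groups in 100 draws, with a simulated control group shared by each pair. Mean r was 0.494, 0.494 and 0.502, with ranges of -0.284 to 0.905, -0.191 to 0.943 and -0.305 to 0.922. Ranges this wide can neither show nor exclude a likeness beyond the shared controls. The covariances were 0.0103, 0.0104 and 0.00314 against simulated means of 0.0146, 0.014 and 0.0149. With the control arrays split 3 and 3, r averaged 0.026, 0.044 and -0.118 over 20 splits. Of the genes that rose, 9 were shared by live and UV-killed F. prausnitzii, where independent lists of those lengths share 0.177, and all 3 L. rhamnosus genes were among the 106 that rose with live F. prausnitzii, where independent lists share 0.0144. UV-killed F. prausnitzii and L. rhamnosus shared 1, the transcript NM_004024, where independent lists share 0.00502. The value for independent lists leaves out the shared controls. The groups simulated as unchanged shared 0 called genes for each pair in 100 draws, which leaves out the effects. With the control arrays split, the 3 pairs shared on average 3.9, 0.6 and 0 genes over 20 splits, and the numbers of genes that rose averaged 61.8 for live F. prausnitzii, 20.1 for UV-killed F. prausnitzii and 0.6 for L. rhamnosus. For genes that fell, no pair shared any.

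Cells without bacteria were also set against the common reference, which differs from them in culture format, oxygen supply and any handling of the filters. The reference was 1 sample and its own spread is left out, and with no dye swap a difference between dyes cannot be told apart from a difference between the cultures. In the filter-grown cells ALB (albumin) was higher by 5.93 ± 0.11 (SE), AFP by 5.48 ± 0.14, AHSG by 4.93 ± 0.12, the transcription factor gene MAF by 4.66 ± 0.17, CHP2 by 4.57 ± 0.14, the motilin gene MLN by 4.08 ± 0.14, FGB by 3.87 ± 0.14, ADH4 by 3.82 ± 0.28, the noncoding MALAT1 by 3.79 ± 0.32 and APOH by 3.76 ± 0.12. They had lower levels of NNMT (-3.43 ± 0.13), FABP7 (-3.42 ± 0.21), the natriuretic peptide gene NPPB (-3.42 ± 0.11), ACTA1 (-3.27 ± 0.14), COL4A6 (-3.24 ± 0.13), CEACAM6 (-3.12 ± 0.13), CNN1 (-3.10 ± 0.21, well above background on 5 of 6 arrays), MYL7 (-3.08 ± 0.16), LTB (-3.08 ± 0.26) and COL1A2 (-3.06 ± 0.23). Adjusted p for these 20 genes lay between 3.33e-22 and 4.38e-10, and each held its direction on 6 of 6 arrays.

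Of 22 cell cycle genes, 21 were lower and 0 higher (median -0.80, adjusted p = 4.51e-08; adjusted p = 0.00174 with an estimated correlation), among them CCNB1 (-1.43 ± 0.07 SE, n = 5) and CDK1 (-1.31 ± 0.08). Of 15 heat shock genes, 13 were lower and 0 higher (median -0.89, adjusted p = 3.17e-07; adjusted p = 0.00174 with an estimated correlation), with HSPA8 at -2.06 ± 0.08 and HSPA1A at -2.02 ± 0.11. Of 18 genes of fatty acid oxidation and PPAR response, 13 were higher and 0 lower (median 0.79, adjusted p = 6.69e-06; adjusted p = 0.0112 with an estimated correlation), with PDK4 at 3.51 ± 0.18. Enterocyte differentiation genes were higher for 16 of 20 and lower for 2 (median 1.29), among them SI (sucrase-isomaltase, 3.56 ± 0.27), APOB (3.36 ± 0.16) and MTTP (2.97 ± 0.27), and the list passed with the preset correlation (adjusted p = 7.5e-06) but not with an estimated one (adjusted p = 0.1). All 10 metallothionein and zinc response genes were higher (median 2.50, adjusted p = 7.5e-06; adjusted p = 0.241 with an estimated correlation), MT1M by 2.92 ± 0.33 and the zinc exporter gene SLC30A1 by 2.86 ± 0.15; the metallothionein probes detect near-identical transcripts, so single members are uncertain.

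**Figure D4:**
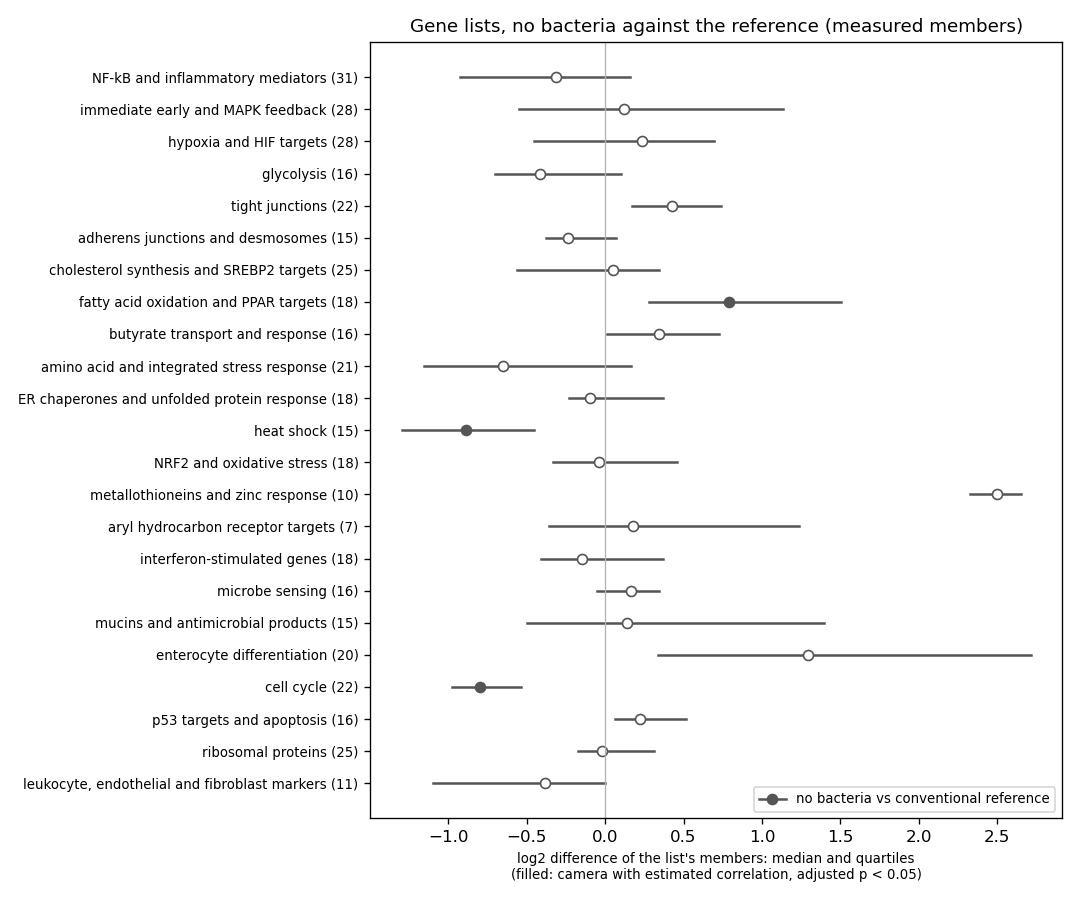
Median (point) and quartiles (line) of the log2 difference of the arrays without bacteria from the common reference over the measured members of 23 gene lists; filled points pass camera with an estimated correlation at an adjusted p below 0.05. The cell cycle list stands at -0.80 and the metallothionein list at 2.50.

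Tight junction genes were higher for 15 of 22 and lower for 4 (median 0.42, adjusted p = 0.0383; adjusted p = 0.0592 with an estimated correlation), AMOTL1 by 1.97 ± 0.14 and CLDN1 by 1.58 ± 0.11. Hypoxia targets went both ways, 15 higher and 10 lower of 28 (median 0.24, adjusted p = 0.754), with NDRG1 at 1.79 ± 0.07, EGLN3 at -1.84 ± 0.15 and HK2 at -1.81 ± 0.17. Glycolysis genes were lower for 9 of 16 and higher for 2 (median -0.42, adjusted p = 0.0432; adjusted p = 0.271 with an estimated correlation), with PFKP at -2.04 ± 0.05. The NF-kB list (median -0.31, 15 lower and 6 higher of 31) and the list of leukocyte, endothelial and fibroblast markers (median -0.39, 7 lower and 2 higher of 11) passed at an adjusted p of 0.0432 each with the preset correlation and not with an estimated one (adjusted p = 0.579 and 0.191). Over all genes 6979 were higher and 6471 lower, 1259 and 1025 of them by at least 2-fold. The split depended on the scaling: median centring gave 3576 higher and 8355 lower against a share of 51.9% higher with loess, and with it the median of all genes lay at -0.21. Because the dye is the same on all arrays, the counts say how many probes departed from equal signal, with dye and culture together.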

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

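Of the tests weighed here, the within-slide test of the NF-kB list with live F. prausnitzii, the test of the aryl hydrocarbon receptor list, the test of scaling on the set of 17 genes and the tests of the L. rhamnosus list at an estimated correlation were chosen after the results they bear on had been seen.

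The NF-kB list was higher with live F. prausnitzii than without bacteria, with 20 of 31 members called. A difference in Cy3 signal strength between arrays is argued against: with log2 median Cy3 signal as a covariate 22 of 31 members were called. The scaling of the arrays is argued against too, since the fewest members called over 4 other scalings was 14, with median centring. Each slide held 1 array of every group, so a shift shared by a slide's arrays cancels from this comparison. The lowest within-slide median was 1.24. A response of the cells to the live bacteria was not argued against. The list was fixed before the data were examined, but these checks used the same arrays as the comparison.

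A set of 17 genes, among them HBEGF, SLC7A5, SPRED1, SERTAD2 and DLL1, was called higher with UV-killed F. prausnitzii than both without bacteria and with live F. prausnitzii. Neither the brightest UV-killed array nor Cy3 signal strength accounts for it: 17 of 17 genes were called in both comparisons without that array, and 17 of 17 with log2 median Cy3 signal as a covariate. Whether the scaling of the arrays is the source of the difference could not be told. All 17 kept both directions under each of 4 other scalings. They had been chosen as calls on the same arrays, which favours that outcome, and the deposited values are themselves loess values. With processed signals, Cy3 alone and the deposited values, 17 of 17 were called in both, with median differences from no bacteria of 1.16, 0.93 and 0.97. The fewest called in both was 1, with median centring, where the spread grew: the median difference was 1.01 ± 0.27 (SE) against 0.90 ± 0.13 with loess. Whether the genes pass thus depends on the scaling. All 17 were highest on the UV-killed array among those of the 3 groups on each of 6 slides. They had been chosen for this pattern, so that count does not test a difference between slides. Each slide held 1 array of every group, so a shift shared by a slide's arrays cancels from both comparisons. Stronger aryl hydrocarbon receptor activity with killed than with live bacteria stays open. The fixed list of its targets was lower with live bacteria at a camera adjusted p of 0.0278 with an estimated correlation. It did not pass without any of live replicates 1, 3, 4 and 5 or UV-killed replicates 2, 4 and 5 (adjusted p from 0.0513 to 0.085). What differs between the preparations was not tested.

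The NF-kB list was also higher with L. rhamnosus than without bacteria, with 2 of 31 members called. At the preset correlation camera gave p = 1e-14 with Cy3 signal strength as a covariate and at most 2.64e-10 without one L. rhamnosus array, but p is so small there that these tests could hardly have failed. With an estimated correlation the adjusted p was 0.03 on all arrays and 0.0989 with the covariate, where the median difference was 0.30 against 0.28; without one L. rhamnosus array it was at most 0.103 (without replicate 3, median 0.27), and 0.0503 without replicate 2 (median 0.19). The adjusted p was 0.053 to 0.08 without any of no-bacteria replicates 1, 4, 5 and 6. The list's median lay below 0 on 1 of 6 slides, which held L. rhamnosus replicate 6 and no-bacteria replicate 1. Within a shared replicate number the median was above 0 for 6 of 6 numbers, from 0.08 to 0.49. The list lay close to the threshold, so its call depends on single arrays. No single L. rhamnosus array carried the whole difference, as the median stayed at 0.19 to 0.34 without each in turn. How much a single array adds stays open, because the adjusted p was above 0.05 without replicate 2 or 3. On replicates 1 to 3 the list means were 0.42 to 0.60 with L. rhamnosus and -0.23 to -0.09 without bacteria. Median Cy3 signals there overlapped, at 125 to 170 and 131 to 200 units, so they were not parted as the list means were. These replicates were singled out after the same list had been seen to be higher on them, and no test was made there. Signal strength therefore stays open, as does a response to the bacterium.

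Splits of the 12 arrays of a comparison into other groups of 6 were counted, 100 of 462 with the real one included. For live F. prausnitzii against no bacteria 1 split, the real one, gave as many as 106 genes and the highest other gave 4; for UV-killed F. prausnitzii 1 gave as many as 38 and the highest other gave 3. For live against UV-killed F. prausnitzii 1 split gave as many as 95 and the highest other 19, and for live F. prausnitzii against L. rhamnosus 1 gave as many as 85 and the highest other 3. For these comparisons no other split drawn gave as many, and 1 in 100 is the lowest share that 100 splits can give. The splits ignored slide and replicate number, so chance with such a structure was not tested. For L. rhamnosus against no bacteria 3 splits gave as many as 3 genes, which is under 5 in 100, but 1 other split gave 89. That split exchanged 1 array of each group and, with many times the real count, points to a structure of the samples beyond the groups.

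Among 275 sets of 6 arrays, 20 held an array far from the other 5, where chance gives about 1 in 20; 9 of the 20 were of UV-killed replicate 6. Its median Cy3 signal was 470 units and its median correlation with its group 0.697. Its list means were 0.0841 for glycolysis, 0.968 for butyrate transport and response and -0.751 for heat shock, and its log ratios 1.37 for SLC7A5, 3.76 for CYP1A1, -1.75 for IL23A and 0.616 for SPRY4. Live replicate 6 had a median Cy3 signal of 257 units, and no-bacteria replicate 1 a median correlation with its group of 0.812. Live replicate 1 was low in CCL20 (2.25) and CXCL8 (1.51), and live replicate 5 high in SPRING1 (0.278). No-bacteria replicate 2 was high in CXCL2 (1.92), and no-bacteria replicate 4 was low in SOD2 (-0.148) and high in KCNJ8 (0.098). UV-killed replicate 5 was low in the NRF2 list (0.157), UV-killed replicate 4 high in IL1B (0.472), and L. rhamnosus replicate 6 high in the cell cycle list (-0.636).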

How the results depend on the processing

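Leaving out the brightest UV-killed array, leaving out the 2 arrays of brightest Cy3 signal, the look at gene lists by replicate number, and the list tests without 1 array or with a Cy3 covariate were chosen after the data had been seen; the cause of the moves below was not tested. Counts of genes changed moved by over 1.5 times as follows. With median centring there were 36 for live F. prausnitzii, 1 for UV-killed F. prausnitzii and 1 for L. rhamnosus against no bacteria, and 14 each for live against UV-killed F. prausnitzii and live F. prausnitzii against L. rhamnosus. Array weights gave, in the same order, 229, 135, 131, 213 and 233, with 33, 27, 64, 69 and 39 of them lower. For UV-killed F. prausnitzii, no background correction and the deposited values each gave 69 and processed signals 72. For L. rhamnosus, processed signals and all probes each gave 5, no filter on dim probes 1, and its 12 arrays alone 0 in limma, where all 24 arrays gave 1277 genes at an unadjusted p below 0.05. The 12 arrays alone gave 45 for live against UV-killed F. prausnitzii and 48 for live F. prausnitzii against L. rhamnosus. The latter comparison gave 85 in the fit of all groups and 143 when the brightest UV-killed array was left out of that fit. Against the reference, 5809 genes also passed 1.5-fold. Without the 2 brightest arrays no count moved by as much.

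Leaving out 1 array at a time gave 91 to 112 genes for live F. prausnitzii, 29 to 46 for UV-killed F. prausnitzii, 1 to 6 for L. rhamnosus, 67 to 100 for live against UV-killed F. prausnitzii, 51 (without L. rhamnosus replicate 4) to 94 for live F. prausnitzii against L. rhamnosus, and 12550 to 12850 against the reference. For L. rhamnosus 9 of 12 such fits moved the count by over 1.5 times: 1 without L. rhamnosus replicates 1, 3 or 5 or no-bacteria replicates 2, 3, 4, 5 or 6, and 6 without no-bacteria replicate 1.

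Replicate numbers were not taken to pair the samples, as not every same-numbered pair correlated at over 0.1 and no label gives a shared source. This rule cannot exclude a shared structure. Of same-numbered pairs 22 of 36 were over 0.1, against 13 of 36 of the same slide and 46 of 148 sharing neither. Median r of deviations from group means across genes was 0.211 (-0.46 to 0.695), -0.05 and -0.048. Of 24 arrays 10 correlated best with their own number. In every group the mean of the metallothionein and zinc list was higher on replicates 1 to 3 (2.35 to 3.68 over the groups) than on replicates 4 to 6 of that group (1.53 to 2.47 over the groups). The mean of the NF-kB list was likewise higher on replicates 1 to 3 without overlap in 3 of 4 groups: -0.23 to -0.09 against -0.67 to -0.55 without bacteria, 0.20 to 0.39 against -0.08 to 0.10 with UV-killed F. prausnitzii and 0.42 to 0.60 against -0.27 to 0.05 with L. rhamnosus. With live F. prausnitzii the ranges overlapped. The amino acid and integrated stress response list parted in the same way in 3 groups and the hypoxia list in 2, and the enterocyte list in the other direction in 2, so the numbers may mark something the samples shared. Within a number, the median difference of the NF-kB list from no bacteria was above 0 for 6 of 6 numbers in each co-culture, from 0.08 to 0.49 with L. rhamnosus. With the number as a block, counts were 68 (3 of them lower) for UV-killed F. prausnitzii, 8 (0 lower) for L. rhamnosus, 147 (29 lower) for live against UV-killed F. prausnitzii and 164 (15 lower) for live F. prausnitzii against L. rhamnosus; with slide and number as blocks, 66 (9 lower) for UV-killed F. prausnitzii and 2 for L. rhamnosus, 1 of them among its 3.

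Of 34 list results that passed camera, 16 passed with an estimated correlation, 22 with median centring and 32 with slide as a block, and 0 reversed. Of the 13 that passed with an estimated correlation between groups, 9 passed without each array of their groups in turn; the receptor target list for live against UV-killed F. prausnitzii and the NRF2 list for UV-killed F. prausnitzii passed in 5 of 12 such fits, and the NF-kB and p53 lists for L. rhamnosus in 6 of 12. With log2 median Cy3 signal as a covariate, those of L. rhamnosus had an adjusted p of 0.0989 each and the other 11 passed. With the control arrays split, the similarity of responses was 0.026 for live and UV-killed F. prausnitzii, 0.044 for live F. prausnitzii and L. rhamnosus, and -0.118 for UV-killed F. prausnitzii and L. rhamnosus. Over 6621 recomputed values of named genes, 6344 kept their direction and side of the threshold, 181 no longer passed, 92 newly passed and 4 reversed. The 4 were against the reference with median centring, which put the median of all genes at -0.21: RPL10A -0.31, SIGIRR -0.16, RPL37 -0.23 and RPLP1 -0.29. That centring also put the median of all genes at -0.10 for live against UV-killed F. prausnitzii.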

Other observations

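Genes outside the fixed lists were also called with live F. prausnitzii against no bacteria, and those named here were chosen after their values were seen. PLAU (urokinase) rose by 1.94 ± 0.22 (SE), RCAN1, a calcineurin inhibitor, by 1.84 ± 0.15, CX3CL1 by 1.81 ± 0.18, the kinase gene MAP3K8 by 1.69 ± 0.20, SERPINA3 by 1.69 ± 0.17 and the oxytocin receptor gene OXTR by 1.68 ± 0.36. HCAR3, a receptor for hydroxylated fatty acids with a near-identical paralog that makes its value uncertain, rose by 1.27 ± 0.14. The ubiquitin-like gene UBD rose by 1.21 ± 0.19, the mucin glycosylation gene GCNT3 by 0.94 ± 0.11 and the transcription factor gene SOX9 by 0.93 ± 0.19. Receptors for prostaglandin E2 (PTGER4, 0.79 ± 0.13) and adenosine (ADORA2A, 0.79 ± 0.13) rose too. Adjusted p in limma was 0.0204 or below for each.

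The transcript NM_004024, chosen after its values were seen and without a matched symbol, was the 1 transcript called in all 3 co-cultures against no bacteria: 1.08 ± 0.16 (SE) with live F. prausnitzii, 1.09 ± 0.16 with UV-killed F. prausnitzii and 0.92 ± 0.16 with L. rhamnosus. With slide as a block it did not pass for L. rhamnosus (adjusted p = 0.202). NCOA7 was called with both preparations of F. prausnitzii, at 0.98 ± 0.11 and 1.17 ± 0.11, and was 0.42 ± 0.11 with L. rhamnosus (adjusted p = 0.608). Of the genes higher with UV-killed bacteria alone among the preparations of F. prausnitzii, GNAI1 (0.76 ± 0.10 against no bacteria), TSKU (0.79 ± 0.14), CCNJL (0.74 ± 0.10) and CITED4 (0.71 ± 0.12), likewise chosen after their values were seen, stood at 0.17, 0.08, 0.18 and -0.02 with live F. prausnitzii.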
